A study of Mus musculus with 4 samples.

How the data were processed

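Single-cell RNA sequencing was done on bone marrow of wild-type mice that carried E0771 cells, a mouse breast cancer line, and had sham surgery or ligation of the femoral artery, which stops the main blood supply of the hind limb. Per the labels' protocols, tumour cells were injected 3 days before surgery, marrow was taken 9 days after it, and cells were sorted by flow cytometry as lineage-negative, cKit-positive cells with or without Sca1, a gate for stem and progenitor cells. Libraries were made with PIPseq, which captures cells in templated droplets without a microfluidic chip, and each replicate carried a hashtag, an oligonucleotide label added to its cells before pooling. The labels do not say whether a replicate is 1 mouse or a pool, so p-values measure the spread between these replicates.

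The deposited matrices hold whole-number UMI counts per gene and barcode, not normalised, with hashtag counts in further lines of the same matrices. The submitters' processing notes name Cell Ranger and the mouse build GRCm38; a version is not given in the sources used here, nor are the counting of reads on the 2 strands and the treatment of reads that match several genes. The treatment label calls 1 library femoral artery ligation and the other sham, whereas the hashtag labels place 2 sham and 2 surgery replicates in each of the 2 libraries and the design text gives 4 replicates per group. Replicates were therefore assigned by hashtag name, and the libraries were treated as batch 1 and batch 2, each holding both groups. In batch 2 the hashtag lines of the matrix list surgery first, unlike its label. Names were used, not order, and wrong names there would exchange the groups of that batch. Every statement about surgery rests on those hashtag names.

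Hashtag lines were kept out of library sizes and gene tests; they made up 22.2% of all counts in batch 1 and 16.1% in batch 2. Barcodes with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrially encoded UMIs were kept, 17065 of 18094 in batch 1 and 13568 of 14179 in batch 2. A mixture of 2 normal distributions was fitted to the log counts of each hashtag, and the midpoint of their means was its minimum; background levels were between 5.6 and 22.8 counts and positive levels between 1588.3 and 1926.1 counts. A single hashtag was found on 86.1% and 90.6% of these barcodes, none on 10.1% and 6.68%, and several on 3.83% and 2.74%; only the first kind was used. Scrublet, run per library, called 0.592% and 0.671% of barcodes as doublets and these were removed. It called 9.02% and 14.2% of the barcodes with several hashtags, so most doublets of cells with the same hashtag would have stayed. Scaling to the total of 10000, 2000 variable genes chosen within libraries, centring within library, 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0 (scanpy 1.11.5, igraph 0.11.9, Python 3.11.15) gave 24 clusters of the 26910 kept cells. A cluster took the name of the class with the highest mean log2 fold of its markers, where at least 3 markers had a log2 fold of at least 1 and no other class had more markers among its top 10 genes. A cluster with a median UMI count under 0.333 of its replicates' medians and none of its class's markers among its top 10 genes also stayed unnamed, which left out cluster 10 (92 cells, ratio 0.276), nearest to erythroid progenitors. Names stand for cells like that class, and 5 clusters stayed unnamed. No cluster took the name macrophage, endothelial or stromal, or epithelial.

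Raw counts were summed per hashtag replicate and class, and 4 surgery sums were compared with 4 sham sums by edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with filterByExpr, TMM scaling, batch as a term and Benjamini-Hochberg adjustment within each of 14 comparisons, those of all cells, 11 classes and 2 unnamed clusters; the eosinophil class had under 10 cells in at least 1 replicate. A gene is said to rise or fall where its adjusted p was under 0.05. CPM are the summed UMIs of a gene scaled by the total UMIs of that replicate and class, without TMM factors, given as mean ± SD over 4 replicates. Fold changes are log2 of surgery over sham ± SE. Gene lists with at least 5 measured members were tested by camera with its preset and with an estimated correlation, and by fry, in limma 3.58.1. Shares of classes, and shares of cells with a UMI of at least 3 genes of the G2 and M phase list after thinning each cell to 2000 UMIs, were compared by two-sided exact permutation tests over 70 splits, for which the smallest possible p is 0.0286. Differences of fold changes between classes were tested as interaction terms in edgeR. Gene coordinates came from GENCODE mouse release 21 on GRCm38, in which 32149 of the 32227 gene identifiers were found; the whole gene span is given, as UMIs were counted per gene.

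The named genes were the 12 highest and 12 lowest fold changes among genes past the threshold with mean CPM of at least 20 and the same sign in both batches, plus up to 4 members of each fixed list with the largest absolute fold change at that CPM. Genes outside this rule are named as chosen after their values were seen. Designs, lists, markers, filters and most alternatives were chosen before the data were examined; a minimum ratio of 16 between the highest and next hashtag counts, clustering without the called genes, and restriction to named clusters were added afterwards. The other alternatives were a stricter cell filter, doublets kept, thinned cells, equal class shares, DESeq2 size factors, DESeq2 1.42.0 in place of edgeR, no low-count filter, no batch term, a block for the replicate number, other clustering settings, and each replicate left out.

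Summed UMIs per replicate were between 19505450 and 51458419. On simulated counts drawn from the replicates' means, with 100 genes changed 1.5-fold and 100 changed 2-fold, the test recovered 80% and 96% in HSC and early multipotent progenitors (10049 genes), 60% and 96% in lymphoid-primed (9510 genes), 100% and 100% in neutrophil-granulocyte (12587 genes) and in monocyte progenitors (12729 genes), 100% and 99% over all cells (16574 genes) and 91% and 100% in erythroid progenitors (10784 genes). Unchanged genes made up 14 of 190, 15 of 171, 13 of 213, 21 of 221, 20 of 219 and 7 of 198 of the genes called there, in the same order. The changed genes were drawn from those with a mean CPM of at least 20. Each gene was simulated alone, without differences between replicates that many genes share, so recovery in the real data may be lower. The scaling by DESeq2's size factors moved the median fold change of all genes by at most 0.0036 in any comparison. A comparison of 1 library with the other, planned for matrices without hashtags, was not used here. Results for some genes are not reported here.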

Results

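Sorted marrow progenitors from 2 captures were analysed, each capture with 2 sham and 2 surgery replicates marked by hashtags, which gave 26910 cells. Batch 1 held 14650 cells and batch 2 held 12260. The batch 1 replicates had 2411 and 5836 sham cells and 2975 and 3428 surgery cells, with medians of 5785, 6840, 7102 and 6262 UMIs per cell. The batch 2 replicates had 3659 and 3188 sham cells and 1890 and 3523 surgery cells, with medians of 10585, 10208.5, 12337.5 and 11398 UMIs. Depth thus differed between the batches and less between groups within a batch. The study asked how ischaemic injury of the limb acts on haematopoietic stem and progenitor cells of tumour-bearing mice.

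Myeloid progenitors made up the largest classes. There were 5025 neutrophil-granulocyte progenitors, with Elane and Prtn3 among the top genes of each of their clusters, and 4885 monocyte progenitors, with F13a1 and Ms4a6c. Haemoglobin genes and Klf1 led 1 cluster of the 3555 erythroid progenitors and Car1 the other. Adgrl4, Hlf, Mecom and Angpt1 led the 1747 HSC and early multipotent progenitors. Flt3, Dntt and Notch1 led the 1513 lymphoid-primed progenitors, which also carried Siglech and Myl10 among their top genes. The other named classes were 2977 B cells, 1416 basophil-mast, 944 megakaryocyte, 420 dendritic cell and 151 eosinophil progenitors, 543 T, NK or innate lymphoid cells and 151 mature neutrophils. Of the unnamed clusters, cluster 2 (1499 cells) had a median of 2678 UMIs and drew 73.0% of its cells from batch 1. Cluster 7 (1337 cells) was led by Cd34 and Ccl9, and cluster 23 (294 cells) by Ighd, Bank1 and Fcer2a.

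**Figure D1:**
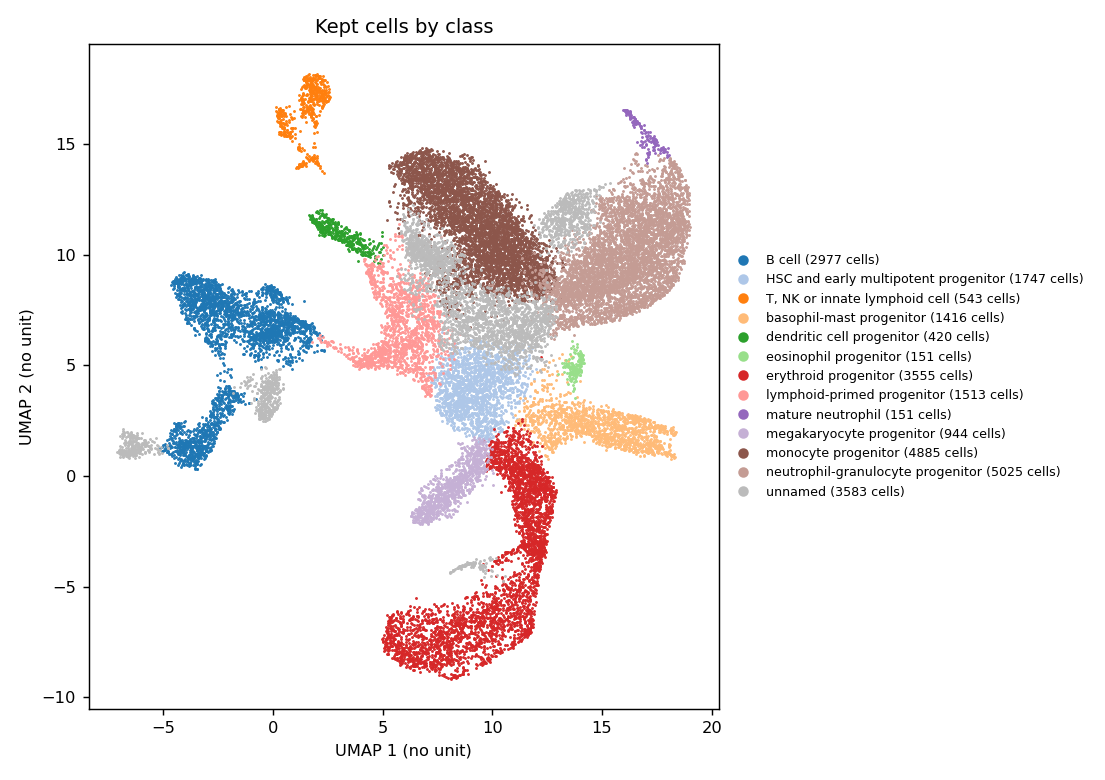
UMAP of the 26910 kept cells, in which each point is 1 cell, the axes have no unit, and colour gives the class named from marker genes or grey for the 3583 cells of unnamed clusters. The 1747 HSC and early multipotent progenitors adjoin the megakaryocyte, erythroid, basophil-mast and lymphoid-primed progenitors, and the 543 T, NK or innate lymphoid cells lie apart.

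Shares of the progenitor classes were compared between surgery and sham to ask whether ligation altered the makeup of the sorted marrow. Neutrophil-granulocyte progenitors were 18.0% ± 1.87 of sham cells and 20.8% ± 6.23 of surgery cells (SD, n = 4 each; exact permutation p = 0.543). They differed by -1.93 points in batch 1 and 7.57 in batch 2. Erythroid progenitors were 13.7% ± 1.44 of sham and 12.3% ± 0.527 of surgery cells (exact permutation p = 0.143), a difference of -1.51 points in batch 1 and -1.28 in batch 2. HSC and early multipotent progenitors were 6.32% ± 0.797 of sham and 6.60% ± 0.885 of surgery cells. Lymphoid-primed progenitors were 5.71% ± 1.84 and 5.17% ± 1.202, with batch differences of 1.46 and -2.55 points. Monocyte progenitors were 17.8% ± 3.10 and 18.4% ± 1.92, with batch differences of 4.14 and -2.81 points. B cells were 11.9% ± 3.13 and 10.6% ± 0.796, and basophil-mast progenitors 5.05% ± 1.01 and 5.17% ± 0.547. Megakaryocyte progenitors were 3.59% ± 0.319 and 3.38% ± 0.498, and T, NK or innate lymphoid cells 2.18% ± 0.850 and 1.82% ± 0.452. Dendritic cell progenitors were 1.48% ± 0.533 and 1.78% ± 0.891, eosinophil progenitors 0.540% ± 0.129 and 0.661% ± 0.363, and mature neutrophils 0.604% ± 0.324 and 0.560% ± 0.273. No class passed the exact permutation test after adjustment over 12 classes, the lowest adjusted p being 0.842, and the sort for cKit and against lineage markers sets these shares.

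Of the 24 clusters, cluster 23 took 1.41% ± 0.347 of sham and 0.603% ± 0.0688 of surgery cells, a difference of -0.726 points in batch 1 and -0.891 in batch 2. Its exact permutation p of 0.0286 is the smallest possible, and its adjusted p over the clusters was 0.686. Of its 294 cells, 286 stayed together when the called genes were left out of the clustering.

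**Figure D2:**
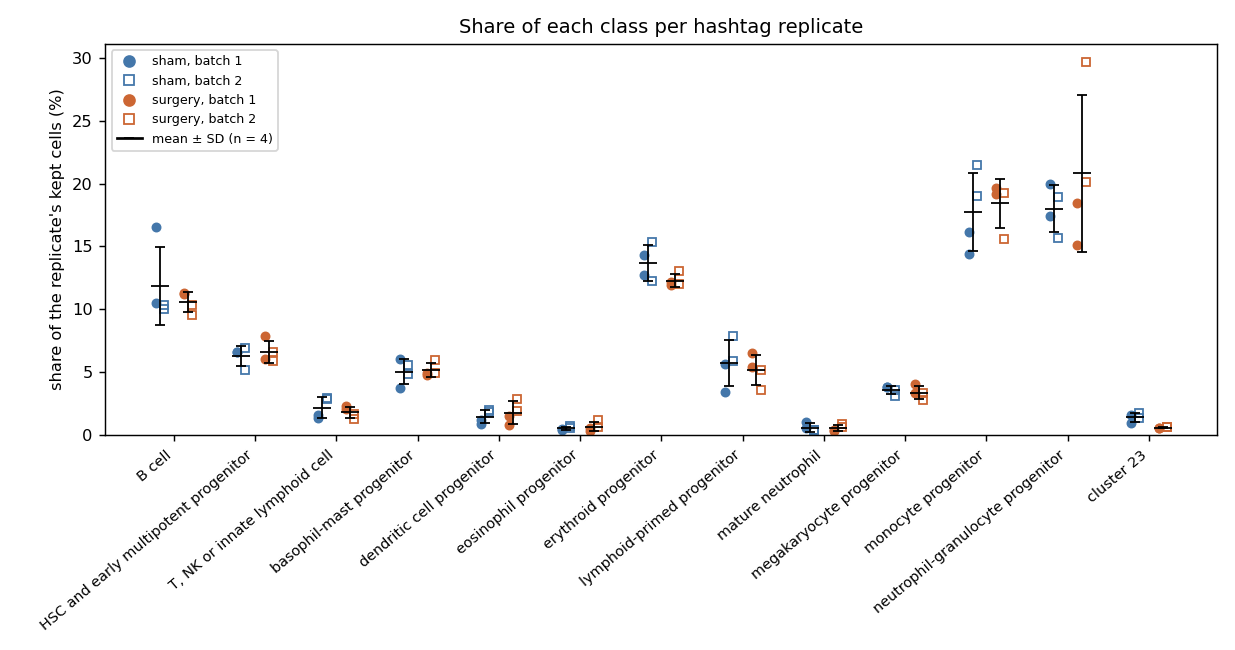
Share of each replicate's kept cells in each named class and in cluster 23 (percent, linear axis), with filled points for batch 1, open points for batch 2, and bars for mean ± SD of 4 replicates per group. The groups overlap in every named class, while the 4 surgery replicates of cluster 23 (0.603% ± 0.0688) lie below the 4 sham replicates (1.41% ± 0.347).

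In the HSC and early multipotent progenitors, which hold the cells the study's question is about, 9 of 10175 genes rose after surgery and none fell at adjusted p under 0.05 in edgeR. Ern1, the endoplasmic reticulum stress sensor IRE1 alpha, rose from 126 ± 22.2 to 211 ± 40.04 CPM (SD, n = 4 each), a log2 fold change of 0.76 ± 0.08 (adjusted p = 1.91e-06). Adam17, the sheddase that releases TNF and other membrane-bound ligands, rose from 91.1 ± 9.39 to 147 ± 19.0 CPM (0.71 ± 0.09, adjusted p = 0.000189). Tap2, a subunit of the peptide transporter that loads MHC class I, rose from 178 ± 4.87 to 236 ± 19.8 CPM (0.42 ± 0.07, adjusted p = 0.00585). Tex2 rose from 69.1 ± 7.94 to 101 ± 3.81 CPM (0.57 ± 0.10, adjusted p = 0.00585). The myosin light chain gene Myl10 rose from 34.0 ± 26.8 to 86.7 ± 34.4 CPM (1.57 ± 0.23, adjusted p = 0.00122). The other 4 lay below the expression minimum of the naming rule and were singled out after their values were seen. They were Thbs1, a secreted matrix glycoprotein (2.87 ± 0.46), Nlrp3, an inflammasome sensor (2.30 ± 0.43), Pgr, the progesterone receptor (1.46 ± 0.22), and Mgst2, a glutathione transferase (1.03 ± 0.20). All 9 were higher in both batches, and all but Myl10 were higher in each surgery replicate than in every sham replicate. Ern1 lies at chromosome 11, 106394650 to 106487852, and Tex2 beside it at 106502147 to 106613423. Adam17 lies at chromosome 12, 21323509 to 21373632, Tap2 at chromosome 17, 34203527 to 34216321, and Myl10 at chromosome 5, 136693146 to 136701094. Ern1, Adam17 and Pgr passed the threshold under every alternative that gave them a value, but 3 of 34 splits of the replicates, this one included, gave at least 9 genes, and the count was 14 without batch 1 surgery replicate 2. The call was kept under 13 of 18 alternatives for Tap2 (highest adjusted p 0.994, with thinned cells), 12 of 18 for Tex2 (0.597, with clustering without the called genes, where the name took 3453 cells) and 7 of 17 for Mgst2 (0.784, likewise). It was kept under 10 of 16 for Nlrp3 (0.292) and 16 of 17 for Thbs1 (0.0804), both highest without batch 1 sham replicate 2, and 17 of 18 for Myl10 (0.807, in DESeq2).

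Because the study's title names haematopoietic ageing, a fixed list of genes linked to HSC ageing was examined in the same class. The list gives no direction per member and holds Cd34, which also served as a marker of early multipotent progenitors. Only 12 of its members passed the low-count filter in this class, which pools HSC with early multipotent progenitors, and most of the list was not measured. Of the 12 measured members, 6 were higher and 6 lower, and the median log2 fold change of the list was 0.0059. Camera did not separate its members from the other genes (adjusted p = 0.873 with the preset and 0.963 with an estimated correlation), nor fry from no change (adjusted p = 0.99). None passed when adjusted over the list alone. Its members with the largest changes were Ramp2 (-0.23 ± 0.15), Selp, the platelet adhesion receptor P-selectin (0.18 ± 0.14), the metallothionein Mt1 (-0.14 ± 0.14) and Alcam (0.13 ± 0.12), each with an adjusted p of 0.9996 in edgeR. The HSC identity list had a median of -0.067 over 9 members (adjusted p = 0.813). Medians were 0.088 over 17 members of the type I interferon list (adjusted p = 0.519) and 0.039 over 15 members of the TNF and NF-kB list (adjusted p = 0.859). The neutrophil-granulocyte list had 13 of 16 members higher and a median of 0.10 (camera adjusted p = 0.00141 with the preset; adjusted p = 0.963 with an estimated correlation). It did not pass without batch 2 sham replicate 1 (adjusted p = 0.0687) or 2 (0.099), without batch 2 surgery replicate 2 (0.043, adjusted p = 0.568), with thinned cells (0.164) or without the batch term (0.115). Cebpa, the transcription factor that opens granulocyte and monocyte fate, passed adjusted over the list alone (0.35 ± 0.08, adjusted p = 0.155 over all genes). The ribosomal protein list was higher in 74 of 90 members with a median of 0.024 (adjusted p = 0.000319; adjusted p = 0.963 with an estimated correlation). It did not pass without batch 2 sham replicate 2 (0.0062, adjusted p = 0.771), batch 2 surgery replicate 1 (0.016, adjusted p = 0.0931) or 2 (adjusted p = 0.3), with thinned cells (0.317), without the low-count filter (0.195) or without the batch term (0.366). Adjusted over the list alone, single members passed in 5 further lists, with Psmb8 (0.24 ± 0.07), Vegfa (1.22 ± 0.30), Ndufa4 (0.25 ± 0.06) and Tap2 upward and Car2 (-0.27 ± 0.08) downward. The share of these cells with G2 and M phase transcripts was 22.99% ± 3.11 in sham and 27.4% ± 5.69 in surgery (exact permutation p = 0.257; adjusted p = 0.914), at median depths of 7236 and 7856 UMIs, a difference of 0.938 points with cells thinned to 1000 UMIs and 8.90 not thinned.

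In lymphoid-primed progenitors, 24 genes were higher after surgery and 6 lower of 9676 tested. Blk, a Src-family kinase of B-lineage cells, rose from 11.4 ± 1.31 to 40.7 ± 17.3 CPM (log2 fold change 1.86 ± 0.23, adjusted p = 2.24e-05 in edgeR). Myl10 rose from 135 ± 37.1 to 401 ± 73.9 CPM (1.66 ± 0.13, adjusted p = 4.42e-09). The interferon-inducible GTPase genes Gbp8 (13.3 ± 6.17 to 48.4 ± 12.9 CPM, 2.07 ± 0.23) and Gbp6 (1.63 ± 0.23) rose, though members of this family are close copies whose reads may not be told apart. Khdrbs3, an RNA-binding protein gene, rose from 28.3 ± 9.96 to 76.4 ± 7.74 CPM (1.56 ± 0.18). Ern1 rose from 143 ± 39.4 to 240 ± 19.4 CPM (0.85 ± 0.11) and Tspan13 from 170 ± 7.77 to 315 ± 72.3 CPM (0.87 ± 0.10). Vegfa, the angiogenic growth factor, rose from 19.9 ± 4.69 to 43.3 ± 6.60 CPM (1.15 ± 0.19, adjusted p = 0.00173). Pgr (1.70 ± 0.20), AA467197 (1.24 ± 0.21), Cass4 (1.18 ± 0.25) and Mgst2 (0.93 ± 0.19) completed the upper set, Mgst2 with 0.080 in batch 1 and 1.30 in batch 2.

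The lower set of these progenitors held Mpo, myeloperoxidase, from 545 ± 41.2 to 420 ± 37.6 CPM (-0.34 ± 0.07, adjusted p = 0.0291 in edgeR). Dpp4 (-0.49 ± 0.10), Btaf1 (-0.52 ± 0.10), Slc9a9 (-0.38 ± 0.08) and Mir99ahg (-0.73 ± 0.14) fell as well. Chosen after their values were seen, Thbs1 (3.28 ± 0.40), Gfi1b (1.44 ± 0.25), Tap2 (0.59 ± 0.09) and Dntt, the terminal transferase of lymphoid precursors (0.50 ± 0.09), rose. Dntt and Flt3 helped to name this cluster and Myl10 is among its top genes. Of its 1513 cells, 1422 kept the name when the called genes were left out of the clustering. At resolution 2.0 the name took 920 cells, with Dntt, Myl10 and Pgr among their top genes. There a cluster of 542 cells with Siglech, Runx2 and Flt3 took the name monocyte progenitor. Without centring within library no cluster took the name lymphoid-primed progenitor. Fold changes were not run in these 2 settings. A shift in the mix of such cells within the class therefore cannot be told apart from a change within cells of the same kind. Myl10, Blk, Gbp8, Khdrbs3, Tspan13, Ern1, Pgr, Tap2, Thbs1 and Gfi1b passed under every alternative that gave them a value. Of 18 alternatives, the call was kept under 17 for Gbp6 (highest adjusted p 0.747, with thinned cells), Dntt (0.217, in DESeq2) and AA467197 (0.0542, without batch 2 surgery replicate 2), 16 for Vegfa (0.336, thinned), 10 for Cass4 (0.828, thinned) and 8 for Mgst2 (0.9998, in DESeq2). In the lower set it was kept under 16 for Btaf1 (0.366), 13 for Mir99ahg (0.0976, with clustering without the called genes), 9 for Slc9a9 (0.57), 8 for Mpo (0.834) and 6 for Dpp4 (0.747), the others highest with thinned cells.

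**Figure D3:**
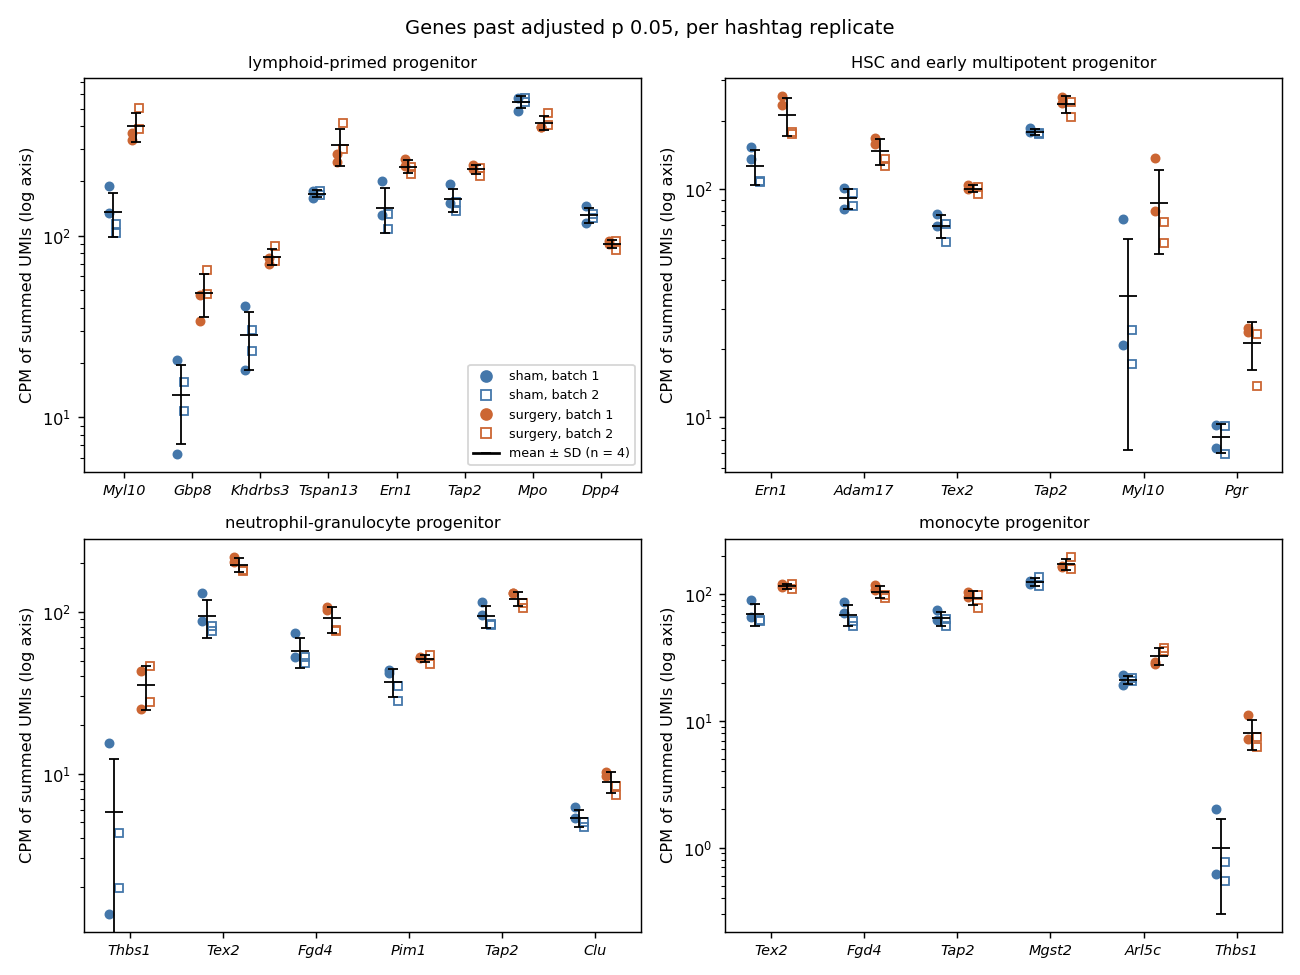
CPM of summed UMIs (log axis) of genes past adjusted p 0.05 in 4 progenitor classes, with 1 point per hashtag replicate, filled for batch 1 and open for batch 2, and bars for mean ± SD of 4 replicates per group; the lower bar of neutrophil Thbs1 runs off the axis. Lymphoid-primed Myl10 (135 ± 37.1 against 401 ± 73.9) and HSC Ern1 (126 ± 22.2 against 211 ± 40.04) separate the groups, while 1 batch 1 sham replicate has HSC Myl10 at 74.0, within the surgery range.

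With the preset correlation of camera, the neutrophil-granulocyte and HSC identity lists were lower in lymphoid-primed progenitors after surgery, and MYC targets and nuclear-encoded oxidative phosphorylation were higher. The neutrophil-granulocyte list had 10 of 13 members lower and a median of -0.25 (camera adjusted p = 7.1e-05; adjusted p = 0.266 with an estimated correlation), with Elane (-0.34 ± 0.09) and Mpo past the threshold adjusted over the list alone. The HSC identity list had 5 of 7 members lower and a median of -0.28 (adjusted p = 0.00131; adjusted p = 0.471 with an estimated correlation). The same list did not pass without batch 2 sham replicate 2 (adjusted p = 0.0618) or batch 2 surgery replicate 2 (0.067). Of its members, 4 passed adjusted over the list alone, the stem-cell transcription factors Hlf (-0.62 ± 0.25), Mecom (-0.48 ± 0.20) and Meis1 (-0.28 ± 0.11) and the glycosyltransferase Gcnt2 (-0.35 ± 0.12). MYC targets and ribosome biogenesis had 17 of 18 members higher and a median of 0.16 (adjusted p = 4.42e-05; adjusted p = 0.266 with an estimated correlation). Nuclear-encoded oxidative phosphorylation had 19 of 21 higher with a median of 0.10 (adjusted p = 4.42e-05; adjusted p = 0.471 with an estimated correlation), which did not pass with clustering without the called genes (0.019, adjusted p = 0.288). The lymphoid list itself had a median of 0.014 over 20 members (adjusted p = 0.118), with Dntt past the threshold both over all genes and adjusted over the list alone. The ageing list had a median of -0.027 and a mean of 0.087 over 9 members (adjusted p = 0.743), with Alcam lower adjusted over the list alone (-0.32 ± 0.09). In the monocyte list (adjusted p = 0.19) Klf4 rose (0.74 ± 0.16, a call kept under 8 of 18 alternatives), and Ctss (-0.31 ± 0.12), F13a1 (-0.42 ± 0.15), Ms4a6c (-0.29 ± 0.09) and Mpeg1 (-0.38 ± 0.09) were lower adjusted over the list alone. The quiescence list had a median of -0.16 over 11 members (adjusted p = 0.017; adjusted p = 0.446 with an estimated correlation). This list did not pass without batch 2 sham replicate 2 (adjusted p = 0.0568), batch 2 surgery replicate 1 (0.0509) or 2 (0.0638), with doublets kept (0.0591), thinned cells (0.116) or clustering without the called genes (0.247). Its members Btg2 (-0.34 ± 0.09) and Egr1 (-0.42 ± 0.13) were lower and Cdkn1a, an inhibitor of the cell cycle, higher (0.35 ± 0.12) adjusted over the list alone. No list passed with an estimated correlation or in fry's directional test in any of the 14 comparisons.

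Neutrophil-granulocyte progenitors had 10 higher and no lower genes of 12727. Tex2 rose from 93.6 ± 24.6 to 195 ± 19.6 CPM (log2 fold change 1.11 ± 0.08, adjusted p = 1.41e-05 in edgeR). Fgd4, an exchange factor for the GTPase Cdc42, rose from 56.9 ± 11.8 to 91.0 ± 16.6 CPM (0.71 ± 0.07, adjusted p = 0.000647). Thbs1 rose from 5.77 ± 6.58 to 35.5 ± 10.7 CPM (3.02 ± 0.41, adjusted p = 0.00795). Pim1, a survival kinase downstream of cytokine receptors, rose from 37.0 ± 7.09 to 51.4 ± 2.68 CPM (0.52 ± 0.08, adjusted p = 0.028). Tap2 rose from 94.3 ± 14.99 to 120 ± 12.5 CPM (0.38 ± 0.05, adjusted p = 0.00581). Clu (0.76 ± 0.12), the secreted chaperone clusterin, Osbpl3 (0.57 ± 0.09), Nckap5 (0.75 ± 0.12), Myl10 (1.38 ± 0.24) and an unnamed transcript beside Thbs1 were also called and were singled out after their values were seen. The ageing list, which holds Clu, had 11 of 15 members higher and a median of 0.11 (camera adjusted p = 0.00231; adjusted p = 0.362 with an estimated correlation). With thinned cells its median was -0.0044 (adjusted p = 0.752), and it did not pass without the low-count filter (0.0676) or without batch 2 sham replicate 2 (0.0945). The neutrophil list had 15 of 20 higher and a median of 0.038 (adjusted p = 0.000659; adjusted p = 0.538 with an estimated correlation), and did not pass without batch 2 sham replicate 2 (0.0084, adjusted p = 0.571) or with thinned cells (adjusted p = 0.159). Cebpa (0.18 ± 0.04), the granule protein gene Ngp (0.62 ± 0.17) and Ctsg (0.11 ± 0.03) passed the threshold adjusted over the list alone, as did F13a1 (0.31 ± 0.07), Tnfrsf1b (0.22 ± 0.06), Ero1a (0.20 ± 0.05) and Pmaip1 (0.63 ± 0.18) in theirs. The AP-1 immediate early list had 11 of 14 higher and a median of 0.21 (adjusted p = 0.00231; adjusted p = 0.538 with an estimated correlation), which was 0.011 without batch 2 surgery replicate 1 (adjusted p = 0.678) and did not pass without batch 2 sham replicate 2 (adjusted p = 0.294) or with thinned cells (0.0782). Tex2 kept its call under every alternative, Fgd4 under 17 of 18 (0.239), Tap2 under 15 (0.826), Thbs1 under 14 (0.207, in DESeq2), Osbpl3 under 11 (0.983, with thinned cells), Nckap5 under 9 (0.9998), Myl10 under 9 (0.462, in DESeq2), Pim1 under 7 (0.5005, with thinned cells) and Clu under 7 of 17 (0.239). The values are the highest adjusted p, reached without the batch term unless another setting is named. The count was 19 without batch 1 sham replicate 1, 2 without batch 2 sham replicate 1, 4 without batch 1 surgery replicate 2, 5 without batch 1 sham replicate 2, batch 1 surgery replicate 1 or batch 2 surgery replicate 2, and 1 without the batch term.

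Monocyte progenitors had 10 higher and no lower genes of 12894. Tex2 rose from 70.02 ± 13.7 to 116 ± 5.21 CPM (0.77 ± 0.08, adjusted p = 0.000182 in edgeR) and Fgd4 from 69.0 ± 13.4 to 104 ± 11.4 CPM (0.63 ± 0.06, adjusted p = 0.000182). Tap2 rose from 64.4 ± 7.91 to 94.0 ± 11.2 CPM (0.55 ± 0.07, adjusted p = 0.00267) and Mgst2 from 125 ± 9.37 to 172 ± 18.0 CPM (0.46 ± 0.06, adjusted p = 0.00674). Arl5c (0.67 ± 0.08), Pmaip1, which encodes the pro-apoptotic protein NOXA (0.42 ± 0.07), and Ikbke, a kinase of the interferon and NF-kB pathways (0.39 ± 0.07, adjusted p = 0.0462), rose as well. Thbs1 (3.24 ± 0.28), Rmnd5b (0.68 ± 0.10) and Myl10 (1.61 ± 0.28) were singled out after their values were seen. In sham, Thbs1 was at 0.990 ± 0.689 CPM and Myl10 at 1.36 ± 0.369, near the floor. The neutrophil-granulocyte list had 16 of 20 members higher and a median of 0.059 (camera adjusted p = 7.78e-08; adjusted p = 0.333 with an estimated correlation). Of its members, 7 passed adjusted over the list alone, among them Elane (0.15 ± 0.03), Mpo (0.098 ± 0.02), Gstm1 (0.20 ± 0.04), Gfi1 (0.23 ± 0.08) and Cebpe (0.29 ± 0.10). The monocyte list had a median of 0.019 (adjusted p = 0.0298; adjusted p = 0.679 with an estimated correlation), which was -0.0062 without batch 1 surgery replicate 2 (adjusted p = 0.636). It did not pass without batch 2 sham replicate 2 (0.13) or batch 2 surgery replicate 2 (0.372), without the batch term (0.175) or with clustering without the called genes (0.0861). Fcgr3 (0.22 ± 0.04), Ccr2 (0.15 ± 0.04) and Psap (0.19 ± 0.05) passed the threshold adjusted over the list alone, as did Tnfrsf1b (0.33 ± 0.07), Vegfa (0.998 ± 0.19) and Ier3 (0.26 ± 0.06) in theirs. G2 and M phase genes were lower in 21 of 22 (median -0.070, camera adjusted p = 0.000208, and adjusted p = 0.679 with an estimated correlation). Their median was -0.0071 without batch 2 surgery replicate 1 (adjusted p = 0.586) and -0.028 with thinned cells (adjusted p = 0.327). The share of monocyte progenitors with such transcripts was 47.7% ± 2.59 in sham and 45.9% ± 4.92 in surgery (exact permutation p = 0.629). It differed by 0.398 points in batch 1 and -3.98 in batch 2. The ageing list was higher in 14 of 18 (median 0.11, adjusted p = 0.00243; adjusted p = 0.315 with an estimated correlation), and did not pass without batch 2 surgery replicate 2 (0.0614) or without the low-count filter (0.128). Tex2 and Thbs1 passed under every alternative that gave them a value, Mgst2 and Fgd4 under 17 of 18 (highest adjusted p 0.103), Tap2 (0.0834) and Arl5c (0.401) under 16, Rmnd5b under 13 (0.157), Pmaip1 under 10 (0.932), Myl10 under 7 of 17 (0.318, without batch 2 surgery replicate 2) and Ikbke under 4 of 18 (0.932, with thinned cells, as for Pmaip1). The count was 6 without batch 2 sham replicate 1 and without batch 2 surgery replicate 2, and 2 without the batch term.

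Across these 4 classes 43 genes were called, 35 of them in 1 class, and Myl10, Tap2 and Thbs1 were called in all 4. Without the low-count filter the counts were 30 in HSC and early multipotent, 64 in lymphoid-primed, 89 in neutrophil-granulocyte and 82 in monocyte progenitors, and with thinned cells 3, 12, 4 and 5. Interaction tests gave a larger change of Ern1 in HSC and early multipotent progenitors than in monocyte progenitors (difference 0.59) and of Adam17 than in lymphoid-primed progenitors (0.99). Tex2 changed more in neutrophil-granulocyte than in monocyte progenitors (0.36), and all 3 differences were past adjusted p 0.05. A call in 1 class alone does not show a change particular to it, as most called genes did not differ between classes. Of the genes called in either class, 2 of 14 differed between HSC and early multipotent and monocyte progenitors. It was 3 of 15 between neutrophil-granulocyte and monocyte and 12 of 37 between lymphoid-primed and neutrophil-granulocyte progenitors, genes not reported here included. The correlation between the batches' fold changes across all tested genes, which are not independent, was -0.117 in HSC and early multipotent progenitors, 0.0692 in lymphoid-primed, 0.0319 in neutrophil-granulocyte and -0.102 in monocyte progenitors and -0.303 over all cells. The change differed between batches at adjusted p under 0.05 for 9, 4, 3, 8 and 0 genes in the same order, where the 0 over all cells stands beside 1433 genes at an unadjusted p under 0.05 in edgeR and was not run in DESeq2.

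Erythroid progenitors gave no gene past the threshold in edgeR or DESeq2, with 425 genes at an unadjusted p under 0.05. The erythroid list had 19 of 20 members lower and a median of -0.12 (camera adjusted p = 6.25e-06; adjusted p = 0.559 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes were lower in 21 of 21 (median -0.065, adjusted p = 6.84e-06; adjusted p = 0.559 with an estimated correlation). The AP-1 list was higher in 14 of 15 (median 0.29, adjusted p = 3.28e-06; adjusted p = 0.559 with an estimated correlation). S phase genes were lower in 20 of 22 (median -0.089, adjusted p = 2.46e-05; adjusted p = 0.57 with an estimated correlation). Without batch 2 sham replicate 1 the medians were -0.014 for the erythroid list (adjusted p = 0.419) and -0.023 for S phase (adjusted p = 0.429). With clustering without the called genes, in which the name took 1845 cells against 3555, none of these 4 lists passed, with medians of -0.012 for erythroid (adjusted p = 0.115), 0.0033 for oxidative phosphorylation (adjusted p = 0.439), 0.020 for AP-1 (adjusted p = 0.437) and -0.019 for S phase genes (adjusted p = 0.115). No gene was called in the megakaryocyte, basophil-mast and dendritic cell progenitors or the mature neutrophils in either tool (399, 339, 107 and 72 genes at an unadjusted p under 0.05 in edgeR). None was called in T, NK or innate lymphoid cells in edgeR (232 at an unadjusted p under 0.05), where DESeq2 called 1. In B cells Myl10 alone rose, from 182 ± 47.0 to 379 ± 73.0 CPM (1.08 ± 0.15, adjusted p = 0.0275 in edgeR), with 328 genes at an unadjusted p under 0.05. The count in B cells was 12 without batch 1 sham replicate 1, 5 without batch 2 surgery replicate 2, and 0 without batch 2 sham replicate 1 or 2 or batch 1 surgery replicate 1 or 2. Cluster 2 had Tex2 (0.90 ± 0.12) and Fgd4 (0.68 ± 0.11) higher, with 0 genes without batch 1 sham replicate 2 and 1 without batch 1 surgery replicate 1. Cluster 7 had Adam17 (0.71 ± 0.08), Tex2 (0.66 ± 0.09) and Tap2 (0.43 ± 0.07) higher, with 5 genes without batch 1 sham replicate 1, batch 1 sham replicate 2 or batch 1 surgery replicate 1.

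Over all cells together, 6 genes were higher and 1 lower of 16794. Myl10 rose from 19.8 ± 6.80 to 45.7 ± 5.50 CPM (1.27 ± 0.16, adjusted p = 0.0413 in edgeR) and Tex2 from 75.1 ± 15.1 to 129 ± 7.504 CPM (0.82 ± 0.09, adjusted p = 0.0335). Fgd4 rose from 51.9 ± 9.80 to 78.0 ± 12.02 CPM (0.61 ± 0.06, adjusted p = 0.0335) and Tap2 from 91.0 ± 9.38 to 119 ± 8.996 CPM (0.41 ± 0.05, adjusted p = 0.0335). Outside the naming rule and chosen after their values were seen, Fyb2 (1.38 ± 0.17) and Pmaip1 (0.47 ± 0.05) rose. Ighd, the constant region of IgD, also chosen afterwards, fell from 9.498 ± 0.720 to 5.999 ± 0.144 CPM (-0.65 ± 0.08), beside the smaller share of cluster 23. Hba-a2 (-0.50 ± 0.21), Cebpa (0.20 ± 0.04), Psmb8 (0.16 ± 0.03), Tnfrsf1b (0.32 ± 0.05) and Fcgr3 (0.20 ± 0.05) did not pass over all genes. Erythroid genes were lower in 20 of 20 (median -0.35, camera adjusted p = 1.36e-10; adjusted p = 0.644 with an estimated correlation), beside the erythroid share of 13.7% in sham and 12.3% in surgery. The neutrophil list was higher (median 0.14, adjusted p = 1.65e-06), as were the ageing list (0.10, adjusted p = 0.0269) and hypoxia and glycolysis (0.051, adjusted p = 0.00707), and the lymphoid list was lower (-0.084, adjusted p = 0.0269). These 4 lists had an adjusted p = 0.644 with an estimated correlation. The ageing list did not pass without batch 1 sham replicate 1 (0.0613), batch 1 surgery replicate 2 (0.13) or with thinned cells (0.244). Hypoxia and glycolysis did not pass without batch 2 sham replicate 1 (0.0983) or batch 1 surgery replicate 1 (0.0884), nor did the lymphoid list without batch 1 sham replicate 1 (0.0896), batch 2 sham replicate 2 (0.209), batch 1 surgery replicate 1 (0.148) or either batch 2 surgery replicate (0.134 and 0.072). With the tested classes held at equal shares, 1 list passed in place of 10, the ageing list (0.057, adjusted p = 0.0215). This setting left out eosinophil progenitors and the unnamed clusters, cluster 23 among them, and used log2 values with an offset of 1 CPM. Changes under it cannot be ascribed to shares alone, least of all for Ighd, which led the omitted cluster 23. The medians then were -0.048 for erythroid (adjusted p = 0.119), 0.043 for neutrophil (adjusted p = 0.117), -0.015 for lymphoid (adjusted p = 0.599) and 0.0024 for hypoxia genes (adjusted p = 0.875), and Ighd (-0.12, adjusted p = 0.9997) and Pmaip1 (0.40, adjusted p = 0.443) lost their calls. The interferon list had a median of -0.061 (adjusted p = 0.736) and the TNF and NF-kB list -0.030 (adjusted p = 0.177). The calls over all cells rest on most of the replicates, as the count was 0 without either batch 1 surgery replicate, without batch 1 sham replicate 2 or without either batch 2 sham replicate, 1 without batch 2 surgery replicate 1 and 3 without batch 2 surgery replicate 2. It was also 0 without the batch term and with the replicate number as a block, and 21 in DESeq2.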

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

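All tests weighed here were chosen after the results were seen. Of 260 groups of 4 replicates, 16 had a replicate far from the other 3, and chance gives about 1 in 20.

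Batch 1 sham replicate 1 stood apart in 7 of these, and for several genes it lay between the other sham replicates and surgery; without it, 19 genes were called in neutrophil-granulocyte progenitors against 10 with it, and 12 in B cells against 1. Average surgery cells counted under its hashtag, equally in each class, would place every such gene at 1 fraction of the way to surgery. The fractions differed over 24 genes called in several classes, with a weighted mean of 0.358 (chi-square heterogeneity p = 0.00192). The error terms and the use of 1 value per gene were settled after a first result was seen. The differing fractions argue against such an equal mixture as the whole cause. Surgery cells whose fraction differs between classes, or that come from particular surgery replicates, were not tested. A mixture together with other differences stays open. Free RNA of surgery cells in the same capture may contribute: over 14 genes, with 1 value each, the median difference in log2 CPM from the other sham replicate of that capture was 0.24, higher in 9 (exact sign test p = 0.424), which leaves it undecided. A difference between the animals was not tested.

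Genes higher after surgery lay close to each other: 37 genes formed 5 pairs within 1000 kb, and a share of 0.0085 of 10000 random gene sets held as many, but for the 3 pairs that neither adjoin within 10 kb nor are close copies it was 0.085, so chance placement of those stays open. Ern1 and Tex2 lie 14.3 kb apart on chromosome 11, and the other pairs are Gbp8 with Gbp6, Cux1 with Myl10, Trpc6 with Pgr, and Thbs1 with an adjoining transcript on the opposite strand. Reads shared between neighbours on the same strand were looked for as pairs within 10 kb on that strand, and there were 0. That limit leaves out Ern1 and Tex2, which lie on the same strand 14.3 kb apart, so shared reads are not excluded for them. The use of strand in the counting is not given, so the pair at Thbs1 cannot be told apart from reads of Thbs1. A strain variant that differs between the groups' mice may raise neighbours together; one that acts in every class that expresses Ern1 and Tex2 is argued against, as both stayed near 0 in erythroid progenitors (-0.027 ± 0.12 and -0.11 ± 0.09; interaction p at most 3.41e-06 in edgeR), while for the other pairs (median over the 3 measured genes -0.035 of the change in the class of the call) and for one that acts in some classes it stays open. Regulation shared between neighbours was not tested.

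Cluster 23, led by Ighd and Bank1, took a smaller share of surgery cells, with a ratio of geometric means of 0.436. With 24 clusters compared, chance could give such a difference (adjusted exact permutation p = 0.686). Cells positive for lineage markers that passed the sort may differ in number between replicates; T, NK or innate lymphoid cells had a ratio of 0.867, and the difference of the log ratios had an exact permutation p of 0.0571, while the ratio was 0.639 in cluster 15, a B cell cluster with Ms4a1 and Igkc (0.314), and 0.926 in mature neutrophils (0.114), so this is undecided. Fewer such cells in the marrow after surgery is a biological alternative that was not tested apart from these.

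In shares, batch 1 sham replicate 1 had 16.5% B cells against 10.01% to 10.5% in the other sham replicates. Batch 2 surgery replicate 2 had 5.99% basophil-mast progenitors against 4.81% to 4.97% in the other surgery replicates, and batch 2 surgery replicate 1 had 15.6% monocyte progenitors against 19.2% to 19.7%. Over all cells, Myl10 was at 37.5 CPM in batch 2 surgery replicate 2 against 47.9 to 49.4, and Ighd at 8.43 in batch 2 sham replicate 2 against 9.71 to 9.95. In HSC and early multipotent progenitors, Myl10 was at 74.0 CPM in batch 1 sham replicate 1 against 17.2 to 24.04, and Mgst2 at 19.8 in batch 2 surgery replicate 2 against 28.0 to 29.3. In the same class, Pgr was at 13.7 CPM in batch 2 surgery replicate 1 against 23.1 to 24.5, and Mt1 at 27.6 in batch 1 surgery replicate 1 against 38.2 to 39.6. In lymphoid-primed progenitors, batch 1 sham replicate 1 had Mir99ahg at 65.9 CPM against 77.1 to 78.3, Fyb2 at 10.3 against 3.44 to 4.08 and Meis1 at 150.4 against 209.7 to 215.5. Batch 2 surgery replicate 2 had Mpo at 476 against 397 to 408.5. In monocyte progenitors, batch 1 sham replicate 1 had Tex2 at 90.4 CPM against 61.2 to 65.5 and Thbs1 at 2.01 against 0.55 to 0.77. Batch 1 sham replicate 2 had Ikbke at 24.8 against 23.4 to 23.5.

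The change after surgery differed between classes for the 41 values given here, in 11 pairs of classes, each by an edgeR interaction term with adjusted p under 0.05. Values are differences of log2 fold changes. In each pair, most genes called in either class did not differ at that threshold. HSC and early multipotent progenitors differed from monocyte progenitors in Ern1 (0.59) and Adam17 (0.63), from erythroid progenitors in Ern1 (0.81) and Adam17 (0.79), and from neutrophil-granulocyte progenitors in Ern1 (0.66), Adam17 (0.73) and Tex2 (-0.56). They differed from lymphoid-primed progenitors in Adam17 (0.99), Mpo (0.44), Tspan13 (-0.56) and Khdrbs3 (-1.14). Lymphoid-primed progenitors differed from monocyte progenitors in Gbp8 (2.47), Khdrbs3 (1.47), Tspan13 (0.81), Ern1 (0.67), Cux1 (0.45), Mpo (-0.43), Tex2 (-0.51) and Fgd4 (-0.96). Against erythroid progenitors they differed in Khdrbs3 (1.76), Gfi1b (1.55), Tspan13 (0.999) and Ern1 (0.89). Against neutrophil-granulocyte progenitors they differed in Khdrbs3 (1.39), Vegfa (1.18), Ern1 (0.74), Tspan13 (0.70), Mgst2 (0.65), Chst11 (0.57), Cux1 (0.51), Mpo (-0.36), Osbpl3 (-0.75), Tex2 (-0.87) and Fgd4 (-1.06). Neutrophil-granulocyte differed from monocyte progenitors in Osbpl3 (0.54), Pim1 (0.42) and Tex2 (0.36) and from erythroid progenitors in Tex2 (1.25). Erythroid differed from monocyte progenitors in Tex2 (-0.89), and B cells from lymphoid-primed progenitors in Blk (-1.26) and Gbp8 (-1.91).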

How the results depend on the processing

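The alternatives with a minimum hashtag ratio, with named clusters alone and with clustering without the called genes were added after the data were seen. The cause was not tested for the changes given here. No called gene changed direction under any alternative that gave it a value. Of the called genes, 3 of 9 in HSC and early multipotent progenitors, 10 of 30 in lymphoid-primed, 1 of 10 in neutrophil-granulocyte and 2 of 10 in monocyte progenitors and 2 of 3 in cluster 7 passed the threshold under every one. None did over all cells, in B cells or in cluster 2. For the log2 fold changes of named genes, 933 values under the alternatives other than leaving out a replicate kept their direction and side of the threshold, 141 lost the call, 25 gained it and 2 changed direction. The 933 include values of genes named from lists that were not called in the main fit. With 1 replicate left out, 694 values kept direction and side, 204 lost the call and 6 gained it. The stricter filter and thinned cells gave no fold changes or gene counts for dendritic cell progenitors and mature neutrophils. Fold changes under these 2 settings and the hashtag ratio kept each cell's class, and thinning used the 1675 of 1747 HSC and early multipotent progenitors with at least 2000 UMIs. Shares, and fold changes with doublets kept or with clustering without the called genes, came from a new clustering, in which a name can cover other cells. With clustering without the called genes, the name HSC and early multipotent took 3453 cells against 1747 and the name erythroid 1845 against 3555. Clusters 2 and 7 were run only with DESeq2's size factors, DESeq2, no low-count filter, no batch term, the block and each replicate left out. Thinned cells gave fewer called genes over all cells and in 4 classes and more in B cells. In the simulated counts, 1.5-fold changes at a mean CPM of at least 20 were recovered at 60% in lymphoid-primed progenitors and 100% over all cells. Those counts hold no differences between replicates that many genes share, so recovery in the real data may be lower.

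For the counts of called genes, the stricter filter gave 3 over all cells, the hashtag ratio 4 and named clusters alone 2. Thinned cells gave 2 over all cells, 3 in HSC and early multipotent progenitors, 12 in lymphoid-primed, 4 in neutrophil-granulocyte and 5 in monocyte progenitors and 3 in B cells. Without the low-count filter the counts were 21 over all cells, 30 in HSC and early multipotent, 64 in lymphoid-primed, 89 in neutrophil-granulocyte, 82 in monocyte, 34 in erythroid, 5 in megakaryocyte and 17 in basophil-mast progenitors. In that setting they were also 49 in B cells, 1 in dendritic cell progenitors, 10 in T, NK or innate lymphoid cells, 6 in mature neutrophils, 16 in cluster 2 and 27 in cluster 7. Without the batch term they were 0 over all cells, 1 in neutrophil-granulocyte and 2 in monocyte progenitors and 0 in cluster 2. DESeq2 gave 21 over all cells, 19 in monocyte progenitors, 5 in B cells and 1 in T, NK or innate lymphoid cells. With doublets kept, basophil-mast progenitors had 1, and with clustering without the called genes T, NK or innate lymphoid cells had 2. Leaving out each replicate gave 0 to 8 over all cells, 7 to 14 in HSC and early multipotent, 2 to 19 in neutrophil-granulocyte, 6 to 13 in monocyte and 0 to 1 in basophil-mast progenitors. It gave 0 to 12 in B cells, 0 to 1 in dendritic cell progenitors, 0 to 1 in T, NK or innate lymphoid cells, 0 to 3 in mature neutrophils, 0 to 3 in cluster 2 and 3 to 5 in cluster 7.

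Leaving out 1 replicate ended calls of genes named in the report as follows. In HSC and early multipotent progenitors, Tap2 lost its call without batch 2 surgery replicate 2 (adjusted p = 0.157) and Tex2 without that replicate, batch 1 sham replicate 2 or batch 2 sham replicate 1 (at most 0.157). Thbs1 lost it without batch 1 sham replicate 2 (0.0804), and Nlrp3 and Mgst2 without any of 5 replicates each (at most 0.292 and 0.151). In lymphoid-primed progenitors, calls ended without batch 2 surgery replicate 2 for Dpp4 (0.33), Btaf1 (0.198), Slc9a9 (0.223), Mir99ahg (0.0894), Cass4 (0.443), Mgst2 (0.198), AA467197 (0.0542) and Klf4 (0.114). Without batch 2 sham replicate 2 they ended for Dpp4 (0.0827), Slc9a9 (0.088), Mir99ahg (0.0557), Cass4 (0.209), Mgst2 (0.213), Mpo (0.0557) and Klf4 (0.104). Mpo lost it without any 1 replicate other than batch 1 sham replicate 2 or batch 2 surgery replicate 2 (at most 0.196), Dpp4 without any other than batch 1 sham replicate 2, and Klf4 also without any batch 1 replicate (at most 0.247). Slc9a9 also lost it without batch 2 sham replicate 1, batch 1 sham replicate 2, batch 2 surgery replicate 1 or batch 1 surgery replicate 2 (at most 0.112). Cass4 also lost it without either batch's sham replicate 1 or batch 2 surgery replicate 1 (at most 0.0703), Mgst2 without batch 2 sham replicate 1, batch 2 surgery replicate 1 or batch 1 surgery replicate 2 (at most 0.189), and Mir99ahg (0.0512) and Vegfa (0.0512) without batch 1 sham replicate 2. In neutrophil-granulocyte progenitors, Clu, Pim1 and Nckap5 lost their calls without any 1 replicate other than batch 1 sham replicate 1 (at most 0.154, 0.128 and 0.121), and Tap2 (0.0605) and Thbs1 (0.0724) without batch 2 sham replicate 1. Thbs1 also lost it without batch 1 surgery replicate 1 (0.0514). Osbpl3 (at most 0.115) and Myl10 (at most 0.251) lost it without batch 2 sham replicate 1, batch 1 sham replicate 2, batch 2 surgery replicate 1 or batch 1 surgery replicate 2, Osbpl3 also without batch 2 surgery replicate 2 and Myl10 also without batch 1 surgery replicate 1. In monocyte progenitors, Ikbke lost it without any 1 replicate other than batch 2 surgery replicate 1 (at most 0.399) and Pmaip1 without either batch 2 sham replicate, either batch 2 surgery replicate or batch 1 surgery replicate 1 (at most 0.266). Myl10 lost it there without any of 6 replicates (at most 0.318) and Rmnd5b without batch 2 sham replicate 1, batch 1 sham replicate 2 or batch 2 surgery replicate 2 (at most 0.157).

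Leaving out each replicate gave list medians of 0.043 to 0.17 for the neutrophil list in HSC and early multipotent progenitors and -0.38 to -0.19 for HSC identity in lymphoid-primed progenitors. In neutrophil-granulocyte progenitors it gave 0.011 to 0.35 for AP-1, 0.0084 to 0.063 for the neutrophil list and 0.083 to 0.13 for ageing. In monocyte progenitors it gave -0.11 to -0.0071 for G2 and M phase genes and 0.077 to 0.13 for ageing, and in erythroid progenitors -0.20 to -0.014 for the erythroid list and -0.15 to -0.023 for S phase. Over all cells it gave 0.054 to 0.11 for ageing, 0.015 to 0.074 for hypoxia and -0.15 to -0.033 for the lymphoid list. Each of these lists lost its call with the preset correlation without at least 1 replicate.

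The replicate numbers were not taken as pairs, as the samples share only a number: the deviations of same-numbered sham and surgery replicates had correlations across genes of 0.0829 in batch 1 and -0.0545 in batch 2 over all cells. Over the 14 comparisons they were between -0.177 (B cells) and 0.166 (monocyte progenitors) in batch 1 and between -0.385 (erythroid) and 0.0747 (neutrophil-granulocyte progenitors) in batch 2. With the replicate number as a block, genes past the threshold were 0 over all cells, 1 in T, NK or innate lymphoid cells and 5 in cluster 7. Lists with the block were 2 in basophil-mast progenitors, 6 in B cells and 6 in cluster 7, and other counts stayed within 1.5 times.

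For lists past the threshold with the preset correlation, thinned cells gave 6 over all cells, 0 in HSC and early multipotent, 2 in neutrophil-granulocyte and 5 in erythroid progenitors and 3 in T, NK or innate lymphoid cells. Equal class shares gave 1 over all cells. With doublets kept there were 5 in HSC and early multipotent and 3 in megakaryocyte progenitors, 4 in B cells, 2 in dendritic cell progenitors, 1 in T, NK or innate lymphoid cells and 3 in mature neutrophils. With clustering without the called genes there were 7, 3, 4, 2, 1 and 3 in the same classes and 2 in erythroid progenitors. Without the low-count filter there were 1 in HSC and early multipotent, 7 in erythroid, 4 in megakaryocyte and 3 in basophil-mast progenitors, 3 in B cells, 2 in dendritic cell progenitors and 9 in T, NK or innate lymphoid cells. Without the batch term there were 0 in HSC and early multipotent, 5 in neutrophil-granulocyte, 0 in megakaryocyte and 0 in dendritic cell progenitors and 3 in T, NK or innate lymphoid cells. The stricter filter gave 2 in megakaryocyte progenitors and 1 in B cells. The hashtag ratio gave 2 in basophil-mast progenitors, 3 in B cells and 0 in dendritic cell progenitors, and DESeq2 size factors 2 in basophil-mast progenitors. Leaving out each replicate gave 0 to 6 in HSC and early multipotent, 2 to 11 in neutrophil-granulocyte, 4 to 13 in monocyte, 3 to 12 in erythroid, 0 to 4 in megakaryocyte and 1 to 3 in basophil-mast progenitors. It gave 1 to 7 in B cells, 0 to 4 in dendritic cell progenitors, 1 to 5 in T, NK or innate lymphoid cells, 0 to 3 in mature neutrophils and 1 to 7 in cluster 7.

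Differences in shares changed sign without centring in HSC and early multipotent progenitors (-0.299 points, where the name took 4325 cells) and with thinned cells in basophil-mast progenitors (-0.131). In mature neutrophils they did so with the stricter filter (0.275, where the name took 1062 cells against 151), doublets kept (0.0399), resolution 0.5 (0.0373), resolution 2.0 (0.234, 587 cells) and clustering without the called genes (0.0208). Those with the stricter filter and resolution 2.0 thus compare other cells. Leaving out each replicate gave -1.88 to 0.299 points in B cells, -0.131 to 0.51 in HSC and early multipotent and -0.32 to 0.458 in basophil-mast progenitors. It gave -0.0705 to 0.642 in dendritic cell, -0.046 to 0.241 in eosinophil and -1.31 to 0.188 in lymphoid-primed progenitors, -0.161 to 0.113 in mature neutrophils, and -0.442 to 1.90 in monocyte and -0.121 to 4.72 in neutrophil-granulocyte progenitors.

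In HSC and early multipotent progenitors the difference in the share with G2 and M phase genes was 8.90 points not thinned, 0.938 thinned to 1000 UMIs, 2.86 with at least 2 and 0.601 with at least 5 genes, and 2.56 to 6.24 without each replicate. Such differences changed sign when not thinned over all cells (3.49 points), in erythroid (0.844) and in megakaryocyte progenitors (2.64). They did so with at least 2 genes over all cells (0.015) and in B cells (-0.478), and with at least 5 genes in B cells (-0.779), erythroid (0.13), lymphoid-primed (-2.04) and neutrophil-granulocyte progenitors (-0.39). Cells thinned to 1000 UMIs gave 0.552 in erythroid progenitors. Leaving out each replicate gave -1.53 to 1.36 over all cells, -2.15 to 3.30 in B cells, -5.53 to 0.709 in erythroid, -3.40 to 0.488 in monocyte and -1.04 to 1.99 in neutrophil-granulocyte progenitors.

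With thinned cells in HSC and early multipotent progenitors, Ramp2 had a log2 fold change of 0.084, Alcam of -0.11, the ageing list a median of -0.087 and the interferon list of -0.012. In the same setting the lymphoid list in lymphoid-primed progenitors had -0.015 and the ageing list in neutrophil-granulocyte progenitors -0.0044. With clustering without the called genes, HSC and early multipotent progenitors had -0.0091 for the ageing list and -0.040 for the TNF and NF-kB list. In that setting T, NK or innate lymphoid cells had -0.0092 for the neutrophil-granulocyte list, which had -0.13 to 1.67 without each replicate. The values were 0.11 for the ageing list in lymphoid-primed progenitors and 0.0033 for oxidative phosphorylation in erythroid progenitors. Without the low-count filter the ageing list had -0.044 in HSC and early multipotent and 0.045 in lymphoid-primed progenitors. With doublets kept the interferon list had -0.038 in the former and the ageing list 0.028 in the latter. Leaving out each replicate gave medians of -0.24 to 0.094 for the interferon list over all cells. In HSC and early multipotent progenitors it gave -0.078 to 0.016 for HSC identity, -0.027 to 0.072 for ageing, -0.026 to 0.17 for interferon and -0.021 to 0.074 for TNF and NF-kB. In lymphoid-primed progenitors it gave -0.053 to 0.10 for ageing and -0.021 to 0.091 for the lymphoid list, and in monocyte progenitors -0.0062 to 0.060 for the monocyte list.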

Other observations

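In T, NK or innate lymphoid cells, genes of the G2 and M phase were lower in 8 of 8 measured members after surgery (median log2 fold change -0.67, camera adjusted p = 6.49e-07; adjusted p = 0.61 with an estimated correlation). Top2a (-0.72 ± 0.24), which untangles DNA, and the mitotic genes Cenpf (-1.37 ± 0.49) and Nusap1 (-0.99 ± 0.34) passed adjusted over the list alone. Over the 428 cells with at least 2000 UMIs, the share with G2 and M phase transcripts was 10.9% ± 4.12 in sham and 7.94% ± 5.79 in surgery. This difference did not pass (exact permutation p = 0.457, adjusted p = 0.914). The neutrophil-granulocyte list had 5 of 5 members higher in these cells (median 1.12, adjusted p = 0.0398; adjusted p = 0.77 with an estimated correlation), but the median was -0.13 without batch 1 surgery replicate 1 (adjusted p = 0.232), and it did not pass without batch 1 sham replicate 1 (0.0758) or 2 (0.44), with doublets kept (0.333) or with clustering without the called genes (0.755). In megakaryocyte progenitors the AP-1 list was higher in 12 of 15 (median 0.17, adjusted p = 0.0244; adjusted p = 0.714 with an estimated correlation). It had 0.0093 without batch 2 surgery replicate 1 (adjusted p = 0.577) and did not pass without batch 2 sham replicate 1 (0.096), batch 1 sham replicate 2 (0.167), batch 2 sham replicate 2 (0.155) or the batch term (0.145). In basophil-mast progenitors ribosomal protein genes were higher in 82 of 91 (median 0.039, adjusted p = 9.8e-10; adjusted p = 0.956 with an estimated correlation). In erythroid progenitors they were lower in 82 of 91 (median -0.043, adjusted p = 4.63e-12; adjusted p = 0.559 with an estimated correlation). Cluster 7 had 14 of 16 neutrophil-granulocyte genes higher (median 0.076, adjusted p = 6.06e-05; adjusted p = 0.621 with an estimated correlation), which did not pass without batch 2 sham replicate 2 (adjusted p = 0.0898). It also had 18 of 22 G2 and M phase genes higher (median 0.12, adjusted p = 0.00178; adjusted p = 0.684 with an estimated correlation), which did not pass without batch 2 sham replicate 1 (0.041, adjusted p = 0.39), batch 1 surgery replicate 1 (0.064, adjusted p = 0.0581) or batch 2 surgery replicate 2 (0.078, adjusted p = 0.512).

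The tests with other splits of the replicates were chosen before the counts were seen. Of the 34 splits of the 8 replicates that a fit with the batch term can estimate, 1, the real one, gave as many genes over all cells (7, highest other 1), in lymphoid-primed progenitors (30, highest other 14), in neutrophil-granulocyte progenitors (10, highest other 3) and in monocyte progenitors (10, highest other 6). A share under 0.05 of these 34 splits thus gave as many for each of these counts taken alone, with no adjustment over the 8 comparisons that had calls. Splits that place unequal numbers of a batch in the groups do not match the design, and without them no share under 0.05 can be reached. Chance is therefore not excluded for these counts. The 18 splits that place 2 replicates of each batch in each group, as the real one does, are too few for a share under 0.05; among them the highest other counts were 1, 14, 2 and 6, and in HSC and early multipotent progenitors 8 against the real 9. That 8 came with the labels of batch 2 exchanged, which gave 0 over all cells, 4 in lymphoid-primed, 2 in neutrophil-granulocyte and 6 in monocyte progenitors. A share above 0.05 of the 34 splits gave as many in HSC and early multipotent progenitors (9, highest other 10, 3 splits as high), B cells (1, highest other 132, 6 splits), cluster 2 (2, highest other 4, 6 splits) and cluster 7 (3, highest other 8, 8 splits). Chance cannot be excluded for these either. The split with 132 genes in B cells gave 286 in erythroid progenitors, where the real split gave 0 and another gave 259. Counts so far above the real one point to a structure of the samples, and what it is was not tested; over all cells that split gave 0 genes. Nor can chance be excluded for lists past the threshold with the preset correlation. Of the splits, 24 gave as many as the 10 over all cells (highest other 15), 31 as many as the 2 in HSC and early multipotent progenitors (highest other 10) and 9 as many as the 9 in lymphoid-primed progenitors (highest other 11). There were 12 with as many as the 8 in neutrophil-granulocyte (highest other 11), 13 with as many as the 8 in monocyte (highest other 12) and 14 with as many as the 11 in erythroid progenitors (highest other 15).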
